A study of Caenorhabditis elegans with 2 samples.

How the data were processed

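Sources were per-peak values from the deposited peak lists, and gene positions and sequence from a reference. The samples are 2 biological replicates of whole young adult Caenorhabditis elegans (66 hours) with an eGFP fusion inserted at hlh-26 and an unc-119 rescue marker, and form 1 group. Chromatin was sonicated to fragments of 200 to 800 bp and precipitated with an antibody against GFP, per the labels.

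The authors deposited 8 peak lists in narrowPeak layout on the ce11 build: for each replicate a ranked list and a thresholded list, and for the series 2 ranked and 2 thresholded lists. Peaks were compared by the irreproducible discovery rate (IDR), a measure of how well a peak's rank recurs between 2 lists. The peak caller, the IDR software, their versions and the control used are not given in the sources used here. Each ranked list carries the local and global −log10 of the IDR as the authors deposited it. The deposited score is the global value rescaled to at most 1000, which held for every ranked peak within 1 unit, so that a score of 540 stands for an IDR of 5.01% and 830 for 1.00%. The deposited signal value is the peak caller's own measure of enrichment. Its scale is not stated, so signal was used only to rank and describe peaks within a list. The lists name no header, and column meanings follow the layout per the labels and the values.

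The main list is the series' conservative thresholded list (90 peaks). All its lines are in the series' ranked list whose 2 compared lists have the peak widths of replicate 1 and of replicate 2, so it compares the replicates with each other. The other series list (75 peaks) belongs to a ranked list with other peak widths, and which 2 lists it compares is not given in the sources used here. Each thresholded list is the part of its ranked list with a score of 830 or more, except for overlapping peaks near the right end of chromosome III that are in the ranked but not in the thresholded lists. Most main list peaks are 524 bp wide, and peaks that overlap each other are counted separately unless stated.

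Genes came from Ensembl release 115 and sequence from RefSeq, both for WBcel235, the same assembly as ce11, with chromosome names translated. Mitochondrial genes without a name took the RefSeq symbol. Coordinates are 1-based. A peak was assigned to the gene whose transcript start was nearest to its summit, or to a short non-coding RNA gene it overlapped. The genes named are those of peaks in the main list that overlap a thresholded peak of both replicates, then those of further peaks by signal until 25 genes were named, every gene of a fixed list assigned to a main list peak, hlh-26 and unc-119. Genes named beyond that rule are said to be chosen after their values were seen, or are host genes or neighbours of a named peak.

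Shares were compared with the remainder, the ranked peaks of the same list that do not overlap the thresholded peaks, by two-sided Fisher's exact test, with exact (Clopper-Pearson) 95% intervals. They were the share of summits from 500 bp upstream to 100 bp downstream of a protein-coding transcript start, of peaks within 200 bp of a tRNA, rRNA, snRNA (SL RNA included) or snoRNA gene, of windows of 50 bp either side of the summit with each of 6 bHLH motifs on either strand, and of peaks on X. The gene lists, 15 in all, were tested with a one-sided Fisher's exact test against protein-coding genes assigned to the remainder. Families of tests were adjusted by the Benjamini-Hochberg method. Overlap between replicates was set against 10000 seeded random draws. Peaks are not independent replicates of the experiment, so these p-values compare classes of peaks in these libraries only, and no test between conditions exists in this design.

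The tests and most alternatives were fixed before the data were examined. The alternatives were another peak list, each replicate alone, the stronger 45 of the 90 peaks, random genome positions as background, merged peaks, other windows, a GC-matched background, other overlap rules, and other distances. Leaving out mitochondrial peaks (for the X and short RNA shares also in each replicate alone), taking ranked peaks with a score of 540 or more (planned only for the number of peaks), and counting other short ncRNA genes were added after seeing the data. The statistics were tested on simulated data. With 20 of 90 peaks planted, the short RNA share, the promoter share and the motif test each found the signal in 100 of 100 simulations, with a false call in 4, 7 and 1 of 100 without it. The gene list test found 8 planted genes in 100 of 100 (1 false call), and the overlap test 5 shared peaks in 20 of 20 (0 false calls). The 8 genes were all planted in the list of collagens and cuticle. For promoters, motifs and gene lists the planted signal was larger than the excess in these data, so power at the observed sizes was not measured. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.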

Results

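HLH-26, a basic helix-loop-helix (bHLH) protein of the worm REF-1 family, was profiled by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans. The animals were young adults at 66 hours and carried an eGFP fusion inserted at hlh-26 by CRISPR, and the precipitation used an antibody against GFP. The data are 2 biological replicates of 1 group, with no second condition, so the comparisons are between replicates and between strong and weak peaks of the same list. Replicate 1 gave 21 peaks past the authors' threshold out of 19393 ranked peaks, and replicate 2 gave 27 out of 24293. The list of both replicates against each other held 90 peaks out of 35301 and is the main list below. The other thresholded list of the series held 75 out of 35468. Peak lists carry no read counts, so the depth behind each peak is unknown, and intervals on shares cover counting error over peaks only.

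The strongest peaks lay on the mitochondrial genome. It carried 14 of the 90 main list peaks (15.6%) but 17 of the 35301 ranked ones. The 10 peaks of highest signal were all mitochondrial, led by a peak in ND5, a subunit gene of respiratory complex I (12171 to 12694, signal 538), and one in COX3, a subunit gene of cytochrome c oxidase (5824 to 6347, signal 534). Others lay over CYTB (4391 to 4914, signal 332), COX2 (9750 to 10273, signal 323), ATP6 (2842 to 3365, signal 322), the small rRNA gene (907 to 1430, signal 312), ND4 (7046 to 7569, signal 303), ND1 (1861 to 2384, signal 280.0), the large rRNA gene (10903 to 11426, signal 251) and COX1 (7845 to 8368, signal 226). Median signal was 307 for the mitochondrial peaks and 93.0 for the 76 nuclear ones. The mitochondrial share was higher in each replicate's own, shorter list, at 13 of 21 peaks in replicate 1 (61.9%) and 15 of 27 in replicate 2 (55.6%).

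**Figure D1:**
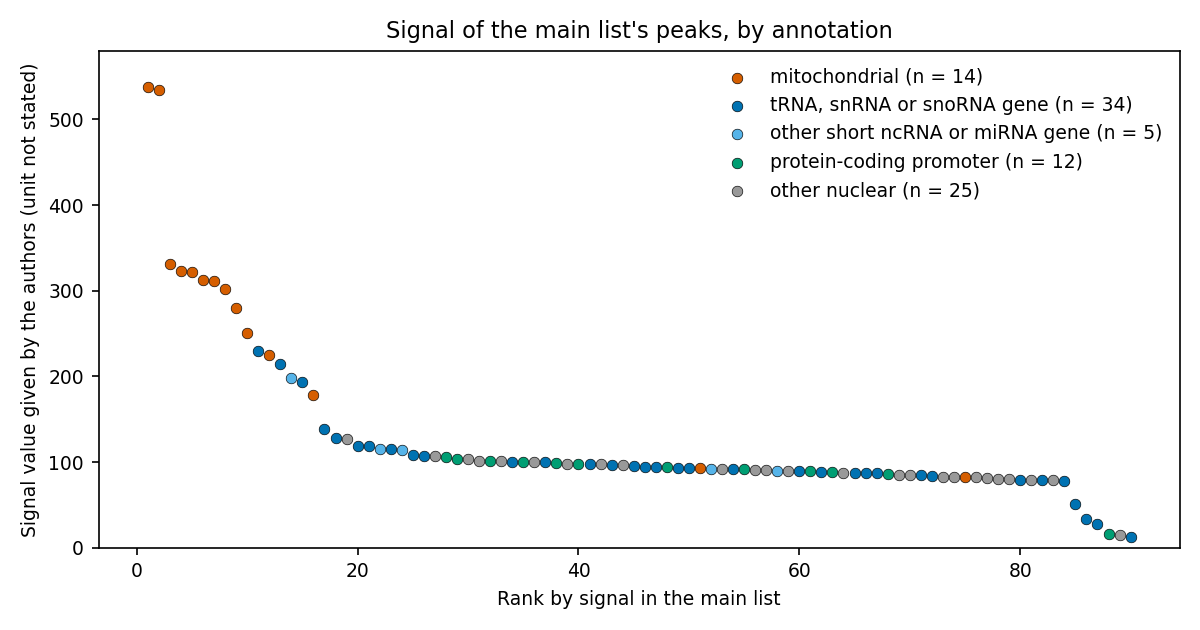
Signal value given by the authors (vertical axis, unit not stated) against rank in the main list (horizontal axis), 1 point per peak, coloured by annotation. Mitochondrial peaks (n = 14) reach 538, and the strongest nuclear peak, at the snoRNA gene C51F7.4, lies at 230.1.

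**Figure D2:**
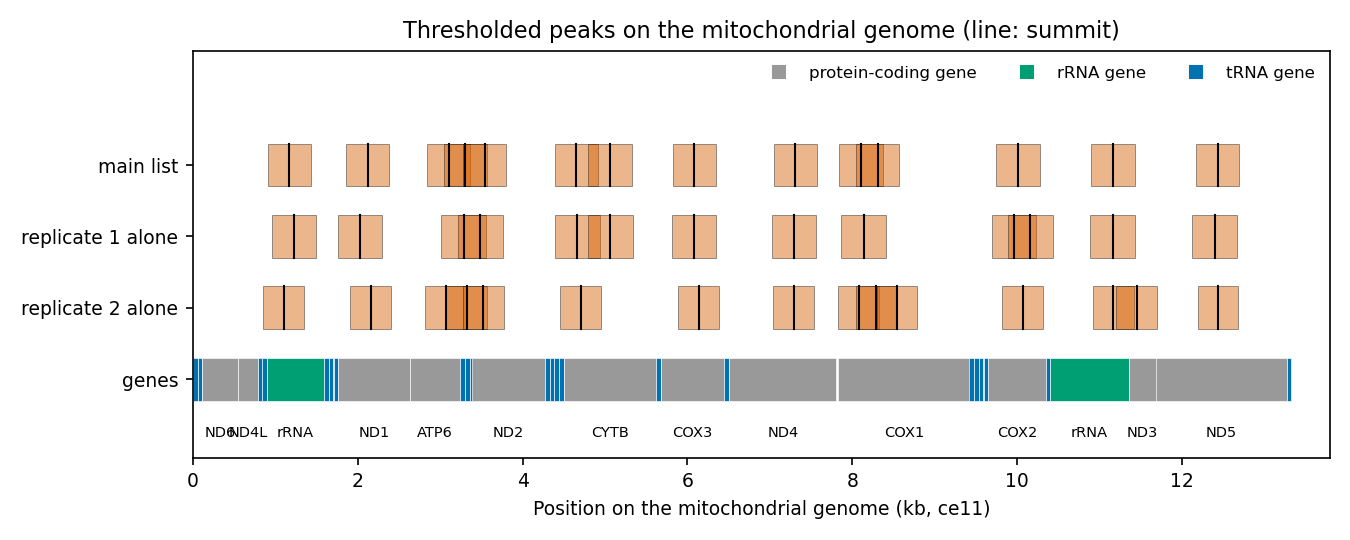
Thresholded peaks along the mitochondrial genome (horizontal axis in kb, ce11) in the main list (14 peaks), in replicate 1 alone (13) and in replicate 2 alone (15), with a line at each summit and the annotated genes underneath. The peaks recur at like positions in both replicates, ND5 and COX3 among them.

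In the nucleus, many peaks lay at genes for short non-coding RNAs. Of the 76 nuclear peaks, 34 (44.7%, exact 95% interval 33.3 to 56.6%) overlapped a tRNA, rRNA, snRNA or snoRNA gene or lay within 200 bp of one, against 2.47% of the 35159 nuclear ranked peaks that did not overlap the main list (odds ratio 32, two-sided Fisher's exact p = 6.74e-34). With mitochondrial peaks counted the share was 43 of 90 (47.8%, 37.1 to 58.6%) against 2.47% (odds ratio 36.1, Fisher's exact p = 6.39e-44). By class, 18 of the 76 nuclear peaks were at snoRNA genes, which guide modification of other RNAs (23.7% against 0.660%, adjusted p = 7.77e-22 over 8 tests), 12 at tRNA genes (15.8% against 1.56%, adjusted p = 5.81e-09) and 4 at snRNA genes (5.26% against 0.253%, adjusted p = 6.73e-05), all by Fisher's exact test. No nuclear peak of the 76 was at an rRNA gene, which allows a share of up to 3.95% by 3 counts of the total and 4.74% by the exact 95% limit. Measured from the RNA gene's 5′ end, the median summit was 7.50 bp inside the gene (quartiles −26.5 and 57.5 bp), and 26 of the 34 lay within 100 bp of that end. These genes are 62 to 165 bp long and peaks were counted only within 200 bp of them. The distances thus do not show a preference for the 5′ end over the rest of the gene. Beyond the few strongest peaks signal did not set this class apart. In 4 groups of 19 nuclear peaks, from highest to lowest signal, the share was 52.6%, 47.4%, 31.6% and 47.4%, and the median signal was 94.2 against 96.3 for the 12 peaks classed as protein-coding promoters. Of the nuclear peaks of each replicate alone, counted after seeing the data, 4 of 8 in replicate 1 (50%, 15.7 to 84.3%) and 8 of 12 in replicate 2 (66.7%, 34.9 to 90.1%) were at such genes.

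Only 4 nuclear peaks were in the main list and overlapped a thresholded peak of each replicate, and all lay at short RNA genes (rpr-1 only in the wider set below) inside introns of protein-coding genes. The first, on chromosome V from 12303571 to 12303750, had its summit in the snoRNA gene C51F7.4 (12303599 to 12303693) and reached the neighbouring snoRNA gene C51F7.3, both in an intron of frm-7. Its signal was 230.1 in the main list, 118 in replicate 1 and 108 in replicate 2. The second lay at the snoRNA gene ZK994.7 in an intron of pxn-1 (V, 8500435 to 8500679), with signals of 215, 121 and 92.1. The third had its summit 2 bp before the start of rpr-1, which encodes the RNA of RNase P, in an intron of ints-8 (I, 13463867 to 13464009), with signals of 198, 112 and 88.8. The fourth lay at the snoRNA gene T03F7.8 in an intron of cutl-18 (V, 11314177 to 11314331), with signals of 194, 110.3 and 77.9. Signals are the authors' values, comparable within a list only.

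**Figure D3:**
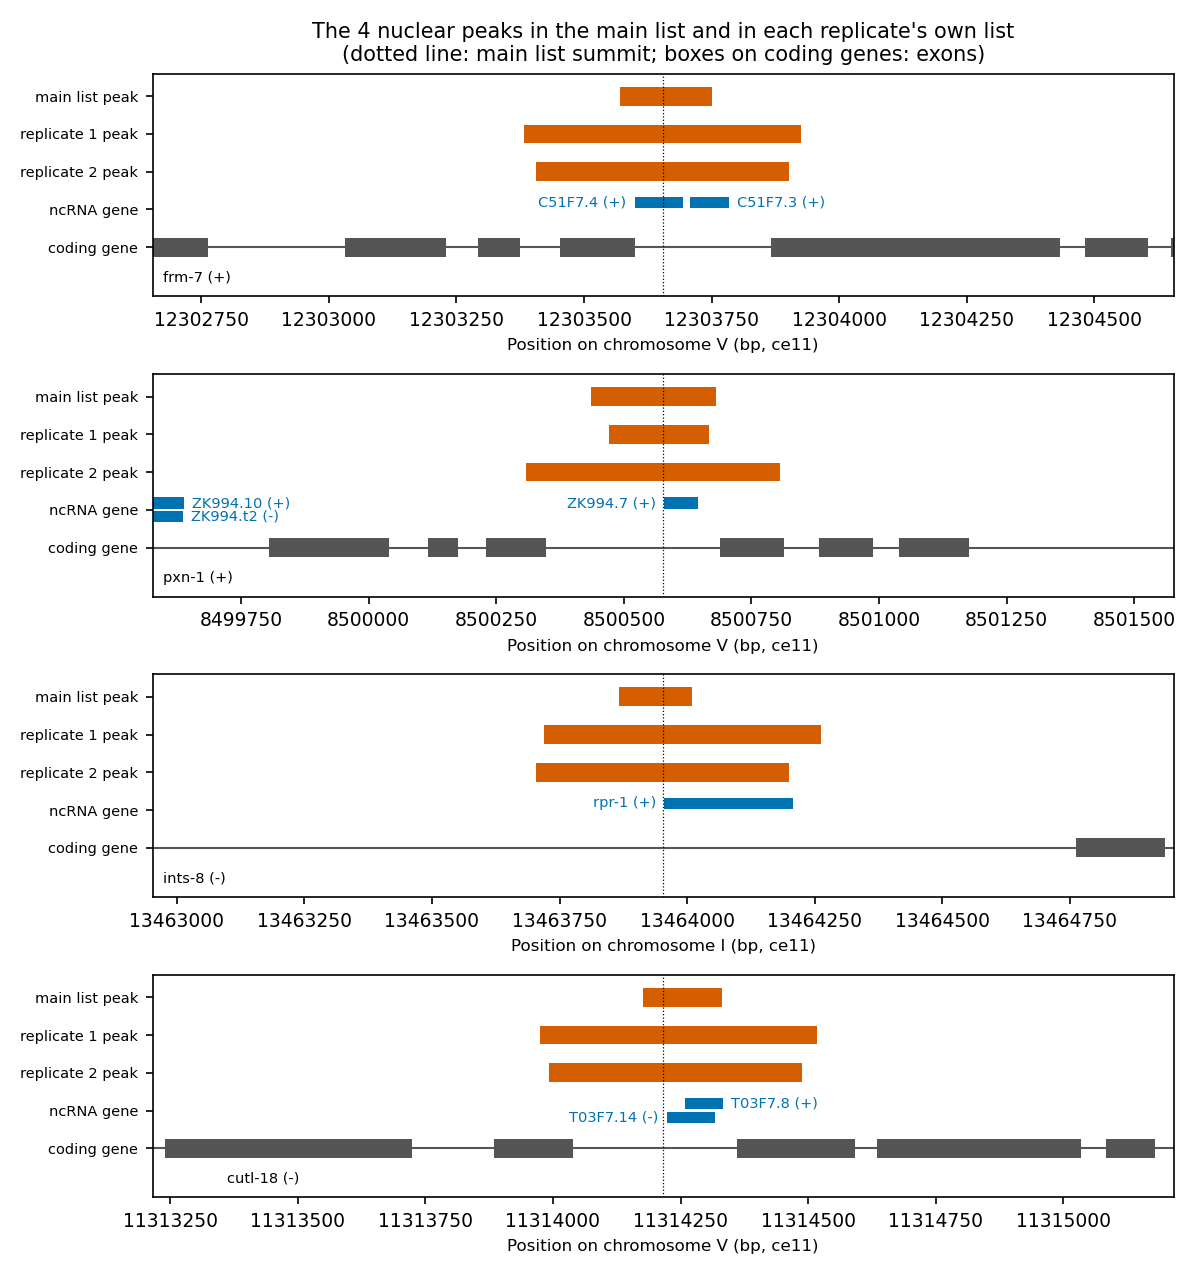
The 4 nuclear loci with a peak in all 3 lists: position in bp (horizontal axis, ce11), peaks of the main list and of each replicate (upper rows), short RNA genes with their strand, and the exons of the host genes frm-7, pxn-1, ints-8 and cutl-18. Each main list summit (dotted line) falls at or just before a short RNA gene and in an intron.

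Next in signal came further RNA genes: the snoRNA genes W03C9.9 (II, 11960614 to 11961137, signal 139), Y75B12B.12 (V, 15190783 to 15191306, signal 129), ZK265.10 (I, 8259304 to 8259827, signal 118.9) and Y23H5B.10 (I, 2514080 to 2514603, signal 116), the tRNA gene C04A11.t1 (X, 13665272 to 13665795, signal 118.6), mrpr-1, which encodes the RNA of RNase MRP (II, 7200058 to 7200581, signal 116), the ncRNA gene F36H1.17 (IV, 11025909 to 11026432, signal 114), and the genes R07E5.16 (III, 10989435 to 10989958, signal 108) and sup-6 (II, 12944534 to 12945057, signal 107), both annotated as snRNA. Among these ranks the exception was mdt-26, a Mediator subunit gene, with a peak in an intron 621 bp after a transcript start (II, 5661553 to 5662076, signal 127). Counting miRNA genes and unclassified ncRNA genes of at most 350 bp, which takes in rpr-1 and mrpr-1 and was chosen after seeing the data, 39 of the 76 nuclear peaks were at a short RNA gene (51.3%, 39.6 to 63.0%) against 10.8% (odds ratio 8.71, Fisher's exact p = 2.55e-18).

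**Figure D4:**
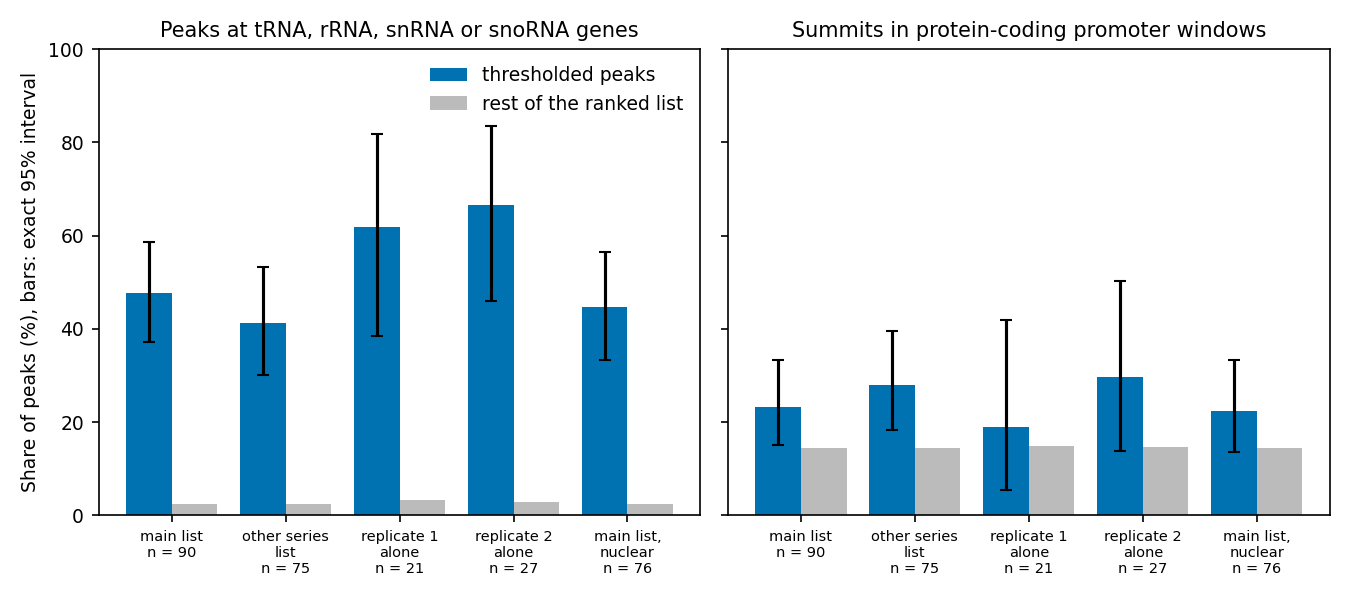
Share of peaks in percent (vertical axes) at tRNA, rRNA, snRNA or snoRNA genes (left) and of summits in protein-coding promoter windows (right), for the main list, the series' other list, each replicate alone and the nuclear part of the main list. Blue bars are thresholded peaks with exact 95% intervals and grey bars the rest of the same ranked list, and the short RNA share runs from 41.3% to 66.7% against 2.47% to 3.20%. All thresholded bars but those of the nuclear part include mitochondrial peaks, which lie among dense tRNA genes, most of all in single replicates.

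Protein-coding promoters held a smaller excess. Summits of 21 of the 90 main list peaks (23.3%, 15.1 to 33.4%) lay between 500 bp upstream and 100 bp downstream of a protein-coding transcript start, against 14.5% of the ranked remainder (odds ratio 1.79, two-sided Fisher's exact p = 0.0239). Without the mitochondrial peaks, an alternative chosen after seeing the data, the share was 17 of 76 (22.4%, 13.6 to 33.4%) and did not pass the test (odds ratio 1.70, Fisher's exact p = 0.0705), and neither did that of replicate 1 alone (4 of 21, p = 0.541). Most promoter peaks were away from these 4 classes of RNA gene: of the 42 nuclear peaks not at a tRNA, rRNA, snRNA or snoRNA gene, 14 lay in a promoter window (33.3%, 19.6 to 49.5%) against 14.5% of like ranked peaks (odds ratio 2.94, Fisher's exact adjusted p = 0.0295 over 21 tests of features). These 14 include mrpr-1 and C14F11.14, and without peaks at miRNA and other short ncRNA genes, set apart after seeing the data, it was 12 of 37 (32.4% against 14.2%, odds ratio 2.90, Fisher's exact p = 0.00393). The 14 and the 12 each include overlapping peaks at hrpu-1 (signals 88.2 and 16.6), counted separately and named after their values were seen. Merged peaks were not tested for these subsets. Examples, chosen after their values were seen, were rpi-2 (IV, 1710977 to 1711500, summit 23 bp upstream of the start, signal 106), kin-14 (I, 7079386 to 7079909, 73 bp upstream), kap-1 (III, 7338534 to 7339057, 39 bp upstream, signal 89.1), a kinesin-associated protein gene that shares the interval with gsp-2, and pde-6 (I, 882473 to 882996, 22 bp upstream, signal 85.9), a phosphodiesterase gene. Replicate 2's ranked list had no peak at the one of rpi-2, and those of kin-14, kap-1 and pde-6 stood at ranks 502, 48 and 598 of 24293 there. The peaks at rpi-2, kin-14 and kap-1 also overlapped an upstream neighbour on the same strand (K08D12.3, mstr-1 and gsp-2). At kin-14 the summit lay in the 3′ UTR of mstr-1. Whether these starts act as promoters was not tested. Coding exons held 16 of the 76 nuclear summits (21.1%, 12.5 to 31.9%), against 37.5% of the remainder (odds ratio 0.444, Fisher's exact adjusted p = 0.0295). By class it was 2 of the 34 at short RNA genes (5.88% against 17.4%, odds ratio 0.297, exact adjusted p = 0.353) and 14 of the 42 away from them (33.3% against 38.0%, odds ratio 0.814, exact adjusted p = 0.783).

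No gene list fixed beforehand stood out among the 78 protein-coding genes nearest to main list summits, against 11551 genes of the remainder. Of the 15 lists, 0 passed at an adjusted p of 0.05 and 1 had an unadjusted one-sided Fisher's exact p below it. That list was collagens and cuticle, with 4 genes (5.13% against 1.14%, odds ratio 4.68, exact p = 0.0131, adjusted p = 0.197). Its members were col-19, an adult cuticle collagen gene with the summit in a coding exon (X, 422047 to 422570, signal 96.2), col-20 (II, 4869976 to 4870499, signal 79.8), col-108 (IV, 1769018 to 1769541, signal 85.1) and col-94, whose peaks lay over the snRNA gene R07E5.16. Ribosomal proteins had rpl-38 (V, 15512753 to 15513276, signal 101) and rps-9 (II, 11125040 to 11125563, signal 83.2), with exact p = 0.0595 and adjusted p = 0.446. The peak assigned to rpl-38 did not overlap that gene and had its summit in a coding exon of lgc-31. The summit assigned to rps-9 lay past the gene's 3′ end. Oocyte and early embryo genes had egg-5, which acts in the oocyte-to-embryo transition (exact adjusted p = 0.775), and its peak lay over the SL2 RNA gene sls-2.4 (I, 4172070 to 4172593, signal 98.1). The other 12 lists had 0 genes and an unadjusted p of 1: the REF-1 family itself, other bHLH factors, the Notch pathway, vitellogenins, heat shock and chaperones, histones, major sperm proteins, intestine, body muscle, neurons, autophagy and lysosome, and translation factors. With 0 genes a one-sided test can give no other p. Each of these lists made up at most 0.303% of the remainder's genes, so 0 of 78 is no evidence of absence.

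Of 6 hexamer motifs of bHLH proteins, 2 were more frequent under the summits than in the remainder. The hexamer CACGCG was found within 50 bp of 6 of the 90 summits (6.67%, 2.49 to 13.9%) against 1.91% of the ranked remainder (odds ratio 3.67), and the N-box CACNAG in 21 (23.3%, 15.1 to 33.4%) against 13.2% (odds ratio 2.00). Both had an adjusted p of 0.0235 over 6 motifs by two-sided Fisher's exact test. The E-box CACGTG was under 4 summits (4.44%, 1.22 to 11.0%, against 2.42%), CATGTG under 6 (6.67% against 3.71%), CATGCG under 3 (3.33% against 2.16%) and CAGCTG under 2 (2.22% against 2.76%), with adjusted p from 0.262 to 1. Main list windows were richer in GC (median 47.5% against 41.6%), and against a remainder matched on GC content neither CACGCG (6.67% against 3.11%) nor CACNAG (23.3% against 17.3%) passed, both with an adjusted p of 0.310. In the series' other list and in each replicate alone, 0 of the 6 motifs passed, adjusted or unadjusted, by Fisher's exact test. These lists are shorter and hold more mitochondrial peaks (20%, 61.9% and 55.6%, against 15.6% of the main list). The odds ratios there were 2.998 for CACGCG and 1.63 for CACNAG in the other list, and 4.19 and 1.15 in replicate 2 alone. In replicate 1 alone 0 and 1 of 21 summits held them. Among the 47 peaks away from short RNA genes CACGCG was under 1 summit (2.13% against 1.85%). There CACNAG was under 10 (21.3% against 13.1%, odds ratio 1.79) and CACGTG under 3 (6.38% against 2.43%, odds ratio 2.74). The lowest exact adjusted p over the 6 motifs was 0.375.

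Chromosome X carried 14 of the 90 peaks (15.6%, 8.77 to 24.7%) against 21.2% of the remainder (odds ratio 0.684, two-sided Fisher's exact p = 0.244), and 9 of these 14 were at short RNA genes such as C04A11.t1. The autosomes had 11 peaks on I, 15 on II, 5 on III, 15 on IV and 16 on V. Mitochondrial peaks cannot lie on X. Without them, an alternative chosen after seeing the data, the share was 14 of 76 (18.4%, 10.5 to 29.0%, odds ratio 0.839, Fisher's exact p = 0.673).

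Neither hlh-26 nor the reference position of unc-119 carried a thresholded peak. No peak of the 4 thresholded lists lay within 2000 bp of hlh-26 (II, 5532839 to 5533742), where the tag was inserted, or of unc-119 (III, 10902641 to 10908935), the gene used as the rescue marker. The unc-119 interval is that of the reference genome, and where the marker copy lies was not examined. The ranked lists had no peak within 2000 bp of hlh-26 either. At unc-119 the ranked list of both replicates had 2 peaks, the stronger at rank 26571 of 35301 (signal 18.1).

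Peaks shared by the replicates' own thresholded lists were mostly mitochondrial. The main list, which compares the replicates with each other, held 76 nuclear peaks of 90. The replicates' own lists compare lists of other median peak widths (570 and 570 bp, and 484 and 500 bp, against 544 and 496 bp). Which lists these are was not established here. The overlap below thus does not count every peak that recurs between the replicates. Of replicate 1's 21 thresholded peaks, 17 overlapped one of replicate 2's 27 by at least 1 bp, against a mean of 0.0321 when replicate 2's peaks were redrawn from its own ranked list (one-sided permutation p = 0.0001, the smallest that 10000 draws can give). Placed at random along the same chromosome they overlapped 9.13 on average and 13 at most (permutation p = 0.0001), because most lie on the short mitochondrial genome. Of the nuclear peaks, 4 of replicate 1's 8 and 4 of replicate 2's 12 overlapped, those at C51F7.4, ZK994.7, rpr-1 and T03F7.8, against a mean of 0.0049 (permutation p = 0.0001). Across the 5717 regions found in both replicates' own ranked lists (19393 and 24293 peaks), Spearman's rho of signal was 0.256. These are not the lists behind the main list, whose ranked list held 35301 peaks. It was −0.0810 over the 1000 shared regions of highest mean rank, a selection that itself lowers rho because it keeps regions high in either list. Regions are not independent replicates, so no p is given.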

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

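Leaving out mitochondrial peaks (also in each replicate alone), the score of 540 or more (planned only for the number of peaks) and the wider set of short RNA genes were chosen after seeing the data. The excess of peaks at short RNA genes held under all 13 alternatives run for it (27.5% to 66.7% of peaks), and the overlap between replicates under all 4 (4 to 17 peaks). The promoter share lost its call in replicate 1 alone (19.05%, with 29.6% in replicate 2 alone), without mitochondrial peaks (22.4%) and with a window of 250 bp upstream to 50 bp downstream (14.4% against 8.27%, odds ratio 1.87 against 1.79 in the main window), and kept it under the other 8. The cause was not tested. The number of motifs passing fell from 2 to 0 in the other series list, in each replicate alone, in the stronger 45 peaks, with windows of 100 bp or 25 bp, with a GC-matched background and without peaks at short RNA genes, with an unadjusted p under 0.05 for 2 motifs in the 100 bp windows and for 0 in the others. Both kept passing with merged peaks, random positions, no mitochondrial peaks, and a score of 540 or more (odds ratios 3.06 and 2.22). The odds ratios of CACGCG and CACNAG, 3.67 and 2.00 in the main list, were 3.67 and 1.88 in the stronger 45 and 3.596 and 1.93 with 25 bp, where counts are fewer. They were 2.59 and 1.71 with 100 bp and 2.22 and 1.46 with GC matched. The cause was not tested. CACGCG (0%, with 7.41% in replicate 2 alone) and CACNAG (4.76%, with 14.8%) changed side in replicate 1 alone, on 0 and 1 of 21 windows, too few to show a direction. Of these 21 windows 13 are mitochondrial. Gene lists passing rose from 0 to 2 among peaks with a score of 540 or more, which raises the peaks from 90 to 287. Each replicate alone gave 21 to 27 peaks. The X share was 0% to 14.8% in the replicates alone, and passed its test in replicate 1 only, where 13 of 21 peaks are mitochondrial and cannot lie on X. Without mitochondrial peaks it was 0 of 8 and 4 of 12 (33.3%) and passed in neither. Spearman's rho was 0.290 with 50% reciprocal overlap and −0.0810 over the 1000 shared regions of highest mean rank. The cause of the first was not tested. Depth is unknown, and lists of 21 and 27 peaks limit what either replicate can show alone.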

Other observations

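Of the tests below, those on shared reads by gene class, on mitochondrial coverage, on exons and on the looser list were chosen after the results were seen. No biological explanation can be set against a second condition in this design. Whether an antibody against GFP recovers these peaks without HLH-26 was not tested, as no other precipitation was used here.

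Over the whole ranked list of both replicates, a peak lay within 200 bp of 417 of the 612 nuclear tRNA genes (68.1%), 177 of the 346 snoRNA genes (51.2%), 59 of the 129 snRNA genes (45.7%) and 105 of the 261 miRNA genes (40.2%). For nuclear rRNA genes it was 3 of 20 (15%), too few to place them. No class was tested against random positions. Starts of protein-coding genes (23.9% of 19973) were close to random positions of tRNA length (23.4% of 10000). In the replicates' own ranked lists tRNA genes stood at 45.9% and 57.5%, against 14.4% and 16.9% of random positions.

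In the looser list of 287 peaks with a score of 540 or more, the nearest genes included 8 for ribosomal proteins (rpl-3, rpl-13, rpl-19, rpl-22, rpl-27, rpl-32, rpl-38 and rps-9; odds ratio 7.53, one-sided Fisher's exact adjusted p = 0.000221) and 13 of collagens and cuticle, among them col-19, col-142, col-176 and dpy-17 (odds ratio 5.15, adjusted p = 8.19e-05). The lone REF-1 or other bHLH gene among them was lin-32 (exact adjusted p = 0.686). The members were named after their values were seen. They were assigned by the nearest transcript start, and whether the peaks lie on these genes was not checked. In the main list the summits assigned to rpl-38, to rps-9 and to col-94, also a member here, lay outside those genes. Of the 287 peaks, 79 were at tRNA, rRNA, snRNA or snoRNA genes.

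Peaks at short RNA genes: for the 18 at snoRNA genes the tables argue against reads shared between gene copies, since 0% of the 36-mers inside these genes recur in the genome (median and highest of 17 genes). For the 12 at tRNA genes and 4 at snRNA genes this stays open: the median gene is repeated over 100% and 42.3% of its 36-mers, but other tRNA genes reach a median of 100% too and only 3 snRNA genes are involved. A test set beforehand, on 100 bp either side of all 34 summits (median 0%), was dropped because a fully repeated tRNA gene fills too little of that window to reach its bound. Transcription by RNA polymerase III from an internal B box (GTTCRANNC) is a candidate explanation. The B box was searched on the gene's strand, in the gene and 50 bp either side, so a hit need not be internal. It was found for 10 of the 19 snoRNA genes within 200 bp of a main list peak (52.6%, exact 95% interval 28.9 to 75.6%). For other snoRNA genes it was 37 of 327 (11.3%, two-sided Fisher's exact p = 3.09e-05). The same search found a B box for 95.9% of tRNA genes. Yet only 12 of 612 tRNA genes lay within 200 bp of a main list peak, against 19 of 346 snoRNA genes. In the whole ranked list tRNA genes led instead (68.1% against 51.2%). This contrast between classes cannot decide, because tRNA genes had a median of 100% repeated 36-mers and snoRNA genes 0%. How shared reads were handled is not known. Among snoRNA genes without a main list peak, 26 of 158 with a ranked peak held a B box. With no ranked peak it was 11 of 169 (two-sided Fisher's exact p = 0.00508). Since 37 snoRNA genes with a B box had no main list peak, a B box alone does not account for which snoRNA genes had one. The explanation stays open for peaks at short RNA genes. Binding of HLH-26 to a motif there met what was set beforehand, an excess over the remainder, for CACGCG (14.7% against 1.91%, Fisher's exact adjusted p = 0.00271), CATGTG (14.7% against 3.71%) and CACNAG (29.4% against 13.2%, exact adjusted p = 0.0208 for both), but stays open, since only CACGCG passed with GC matched (exact adjusted p = 0.0128, others 0.0968 and 0.204) and none did against remainder peaks at short RNA genes (lowest 0.0950, CACGCG at 4.15% there).

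Mitochondrial peaks: reads shared with nuclear copies are argued against, since 0% of the 2324 36-mers within 100 bp of the mitochondrial summits occur on a nuclear chromosome. Ranked peaks covered 53.5% of the mitochondrial genome in 1 replicate and 54.8% in the other, against 10.1% and 8.72% of the nuclear genome. More mitochondrial DNA in the precipitated libraries than in the control could give such coverage and may be the source of these peaks. Coverage cannot decide it, because it is made of the peaks themselves and local binding at the same places would give the same value. The bound it met was set after the results were seen. The rest of that genome had no ranked peak, and thresholded peaks recurred at like positions in both replicates. Local binding within that genome stays open, as it was not tested.

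Nuclear peaks away from tRNA, rRNA, snRNA and snoRNA genes: exons of protein-coding genes held 45.2% of the 42 summits against 43.2% of the remainder (Fisher's exact p = 0.876). Without the 5 at other short ncRNA or miRNA genes it was 51.4% of 37 against 45.4% (Fisher's exact p = 0.511), so an excess over transcribed exons such as those of col-19 and col-20 was not detectable with so few peaks. Promoter binding by HLH-26 and open promoters in general were not told apart by any test here.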
